A study of Mus musculus with 4 samples.

How the data were processed

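ATAC-seq libraries of mouse periosteal stem/progenitor cells after 3 days of osteogenic induction were compared between 2 control and 2 Plagl1 knockout libraries. The submitters' processing notes name Trim Galore 0.6.10, Bowtie2 2.5.4, GATK 4.5.5.0, SAMtools 1.21, deepTools 3.5.5, DiffBind 3.16.0, HOMER and the build mm39, without role or order. The peak caller, the shift of reads for the transposase and the normalization of libraries are not given in the sources used here.

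There were 2 tables. The first holds 85925 consensus peaks with the log2 fold change, the mean log2 CPM, the F score, the p-value and the FDR of the edgeR comparison, all computed by the authors, per the file headers. The second holds 15221 of these peaks with an annotation in the layout of HOMER (region, distance to the nearest start site and gene), as deposited. Tested on the values, its peaks are those with a p under 0.05 and an absolute log2 fold of at least 0.2, so 1834 peaks with p under 0.05 carry no gene, and 169 of them passed the FDR (24 gained, 145 lost). Genes are therefore known only for peaks with p under 0.05, and classes and lists were tested among annotated peaks and their 8173 genes, not among all consensus peaks as planned. For the same reason no count adjusted over a gene list alone is given. For the Klf4, Irx5 and Ctsk loci such a count is given only for peaks within 50 kb of a start site, because loci bounded by their annotated peaks would be chosen by p.

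The deposited FDR equals the Benjamini-Hochberg value over all peaks to within 6.73e-06. The deposited log2 CPM sums to 1.02e+06 on the linear scale. The standard error of each fold was computed as the absolute log2 fold over the square root of F. The deposited p-value follows from F as a chi-square on 1 degree of freedom (median ratio 0.999, and 98.1% of peaks within 0.05 of 1). The log2 standard error fell on log2 CPM with a slope of -0.52 and an r squared of 0.997 over 81527 peaks with F of at least 0.01, and counting noise alone gives -0.5. The spread used by the deposited test therefore followed signal almost alone, with a slope near that of counting noise. A spread of a peak's own between libraries barely entered it, which is the main limit on every call reported. The level of the spread cannot be set against counting noise, because the depth of each library is unknown. Values per library, their depth and their agreement are not analysed here, and 0 columns of unassigned libraries were set aside. The annotated peaks are labelled gain (8628) or loss (6593) by the authors, without the genotype that gained. The direction of the fold is not otherwise stated in the labels or headers, and positive values are read as higher in the knockout.

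A peak was called gained or lost at a deposited FDR under 0.05 with no minimum fold. Promoters were peaks within 1 kb of a start site. Genomic classes, gene lists and sex chromosomes were tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment within each family, and shares carry exact Clopper-Pearson 95% intervals that cover counting error only. List medians were placed among 10000 random lists. Start sites were solved from the deposited distances. Gene symbols of the transcripts that host an intron came from the RefSeq table of assembly GRCm38.p6, used for names alone, and 9122 of 9128 annotated peaks with a transcript were matched. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

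The rule for named genes, fixed before the data were examined, took all annotated peaks of Plagl1, Klf4, Irx5 and Ctsk, the 10 gained and 10 lost peaks with the largest absolute fold among called peaks above the median signal (1 per gene), and up to 3 genes with the smallest FDR from each of the 23 lists. The groups, the tests, the lists and most alternatives were also fixed then. Added after seeing the data were the subtraction of a running median of the fold over 2000 peaks along signal, the comparison of gained with lost peaks per list, the removal of repeats, the turned ratio, the peaks within 50 kb of the Klf4, Irx5 and Ctsk start sites adjusted alone, the stricter FDR for the direction, assumed coefficients of variation of 0.05, 0.1 and 0.2 between libraries, and the second myeloid, second mesenchymal, lymphocyte, and erythroid and megakaryocyte marker lists.

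The procedures were tested on simulated data for the comparison of all 85925 peaks. Of 200 simulated peaks with a log2 fold of 0.5, 34.5% were called, and of 200 with a log2 fold of 1, 78.5% were called, at the implied standard errors and with the observed trend of fold with signal. Beside the 69 and 157 simulated changes found, 15 and 36 unchanged peaks were called. With the trend subtracted these were 3 and 8 beside 63 and 154, so in this simulation the trend alone raised the false calls above the nominal 5%. Only 200 peaks were changed per simulation, so the p threshold after adjustment was stricter than in the data, where 4833 peaks passed. Both the detection rates and the shares of false calls may therefore differ from those of the data. With calls shuffled over the 15221 annotated peaks of 8173 genes, 3 of 920 list tests passed, with adjustment within each of 20 draws. A list with 60% of its genes gained passed in 20 of 20 draws. The shuffle does not keep the calls of 1 gene together, so it does not cover clusters of changed peaks within genes. Motifs were not analysed here, because no mm39 genome was used.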

Results

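Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in periosteal stem/progenitor cells of the mouse mandible. The cells came from the mandibular angle of mice aged 8 weeks and were held for 3 days in osteogenic medium with ascorbic acid, β-glycerophosphate and dexamethasone. There were 2 control libraries (floxed Plagl1 without Cre) and 2 libraries in which Ctsk-iCre, a Cre driven by the cathepsin K gene, was combined with floxed Plagl1 (the knockout). Plagl1 encodes a zinc finger transcription factor and is an imprinted gene. The authors' deposited table held 85925 consensus peaks with a median width of 464 bp (130 to 4067 bp) and a median signal of 5.51 CPM. Values per library are not analysed here, because the table gives 1 fold, 1 F statistic and 1 p per peak, so the depth of each library is unknown. The labels do not say whether libraries of 1 genotype came from separate animals, so no p-value given here covers variation between animals. A positive fold is read as higher in the knockout, and the tables' labels, which include gain and loss, do not name the genotype that gained. With the ratio turned, gained and lost would change places in every count and share below.

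The first comparison asked which regions differed in accessibility between the knockout and the control libraries. Peaks near macrophage and osteoclast genes were among those that gained accessibility, and peaks near extracellular matrix and WNT pathway genes were among those that lost it. In the authors' deposited table, 4833 of the 85925 peaks (5.62%) had an edgeR FDR under 0.05, of which 2699 were gained and 2134 were lost. The gained share was 55.8% (exact Clopper-Pearson 95% interval 54.4 to 57.3%, counting error only), or 44.2% with the ratio turned. Gained peaks of the authors' deposited table had a median log2 fold of 0.57 (1.48-fold) and lost peaks of -0.38 (0.770-fold). Of the 270 called peaks with an absolute log2 fold of at least 1, 229 were gained and 41 were lost in the authors' deposited table. Fold and signal were related across peaks: the median log2 fold was 0.12 in the weakest 10% of peaks, with 112 gained and 16 lost, and -0.06 in the strongest 10%, with 194 gained and 654 lost. With this trend subtracted, 2727 peaks were gained and 1328 lost, a gained share of 67.3%. The standard error implied by the deposited F fell with mean signal as counting noise would (slope of log2 standard error on log2 CPM -0.52, where counting alone gives -0.5, r squared 0.997), so the spread between a peak's own libraries barely enters these calls. If libraries of 1 genotype varied by an assumed coefficient of variation of 0.05 on top of the deposited standard error, 1341 peaks would pass. With 0.1 it would be 55, and with 0.2 it would be 0, against 17055 peaks at an unadjusted deposited p under 0.05.

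**Figure D1:**
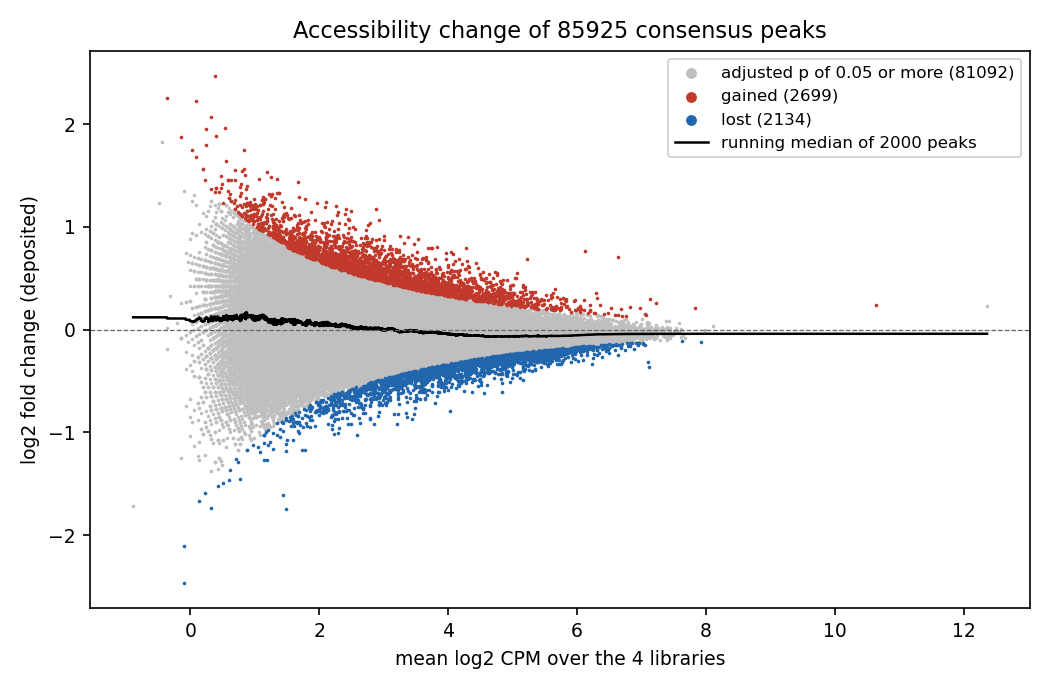
Log2 fold change (y axis) against mean log2 CPM over the 4 libraries (x axis) for each of 85925 consensus peaks as deposited by the authors. Red points are the 2699 gained and blue points the 2134 lost peaks, and the black line, a running median over 2000 peaks, falls from above 0 among weak peaks to below 0 among strong peaks.

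Among called and annotated peaks above the median signal of 5.51 CPM, counted with 1 peak per gene, the largest gains lay near Gm1653, Rassf4, Mir5127, Kcnk13, Ptpro, Gm4827, 1700027F09Rik, Tmsb4x, Cblc and Sost. Their log2 folds ran from 0.97 to 1.17 in the authors' deposited table. The Rassf4 peak lay in intron 1 of 10 (chromosome 6, 116649343 to 116649661, mm39) with a log2 fold of 1.15 (SE 0.185 implied by the F) in the authors' deposited table. Kcnk13, a potassium channel gene, had a gained peak in intron 2 of 2 (chromosome 12, 99973016 to 99973443) with a log2 fold of 1.06 (SE 0.160) in the authors' deposited table. Sost, which encodes the WNT inhibitor sclerostin, had a gained peak in its only intron (chromosome 11, 101856466 to 101856859, 1179 bp from the start site) with a log2 fold of 0.97 (SE 0.170, FDR 1.50e-05) in the authors' deposited table. Under the same limits the largest losses lay near Wwc1, 4933406I18Rik, Gm20125, Bcas3, Rcan2, E230013L22Rik, Cdk14, Kif21a, Mansc1 and Cst3, with log2 folds from -1.03 to -0.85 in the authors' deposited table. The Wwc1 peak lay in intron 1 of 22 (chromosome 11, 35823178 to 35823777) and fell to 0.491-fold (log2 -1.03, SE 0.191) in the authors' deposited table. Cst3, which encodes the protease inhibitor cystatin C, had a lost peak in intron 1 of 2 (chromosome 2, 148714848 to 148715176) with a log2 fold of -0.85 (SE 0.143) in the authors' deposited table. The peak assigned to E230013L22Rik lay inside Col4a2, a basement membrane collagen gene, in intron 20 of 47.

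The second comparison concerned the deleted gene and the genes named with it in the series title. The authors' annotation assigned no peak to Plagl1 among its 15221 annotated peaks. No peak assigned to Plagl1 therefore had a p under 0.05 with an absolute log2 fold of at least 0.2. Peaks short of that rule carry no gene and the Plagl1 start site was not located, so the deletion was not checked here. Irx5, a homeobox transcription factor gene, lost accessibility at both of its 2 annotated peaks, where annotation itself required a p under 0.05 and an absolute log2 fold of at least 0.2. The promoter peak (chromosome 8, 93083935 to 93084666, -124 bp from the start site, 33.4 CPM) had a log2 fold of -0.44 (SE 0.0774, FDR 1.59e-05) in the authors' deposited table. The other, 148053 bp downstream of the start site (93231990 to 93232964), had a log2 fold of -0.60 (SE 0.194, FDR 0.0401) in the authors' deposited table. Within 50 kb of the Irx5 start site, 1 of 3 consensus peaks was lost and 0 were gained, with a median log2 fold of -0.0875. The unannotated peak beside the promoter (93082419 to 93083253, mean log2 CPM 6.03 against 5.06 at the promoter peak) did not pass and had a log2 fold of -0.0875 (SE 0.0552, p 0.113) in the authors' deposited table. Neighbouring homeobox genes of the cluster had 1 called peak each, both lost: -0.48 (SE 0.138, FDR 0.0180) at a peak assigned to Irx3 inside Fto, in intron 8 of 8 (92342043 to 92342877, 185822 bp from the Irx3 start site), and -0.68 (SE 0.206, FDR 0.0281) at the only annotated peak of Irx6 (93344879 to 93345343), both in the authors' deposited table and named after their values were seen. Within 50 kb of the Irx3 start site, 0 of 4 consensus peaks passed the edgeR FDR, and the peak over that start site (92527598 to 92528992) had a log2 fold of -0.13 (SE 0.0623, FDR 0.222) in the authors' deposited table. Of the other 3 annotated Irx3 peaks, none passed, and 1 had a fold above 0 (0.87, SE 0.434). Of the 92 consensus peaks between 92 and 94 Mb of chromosome 8, 7 were lost, including 1 assigned to the matrix protease gene Mmp2, and 1 was gained at the edgeR FDR, with a median log2 fold of -0.08, in the authors' deposited table.

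**Figure D2:**
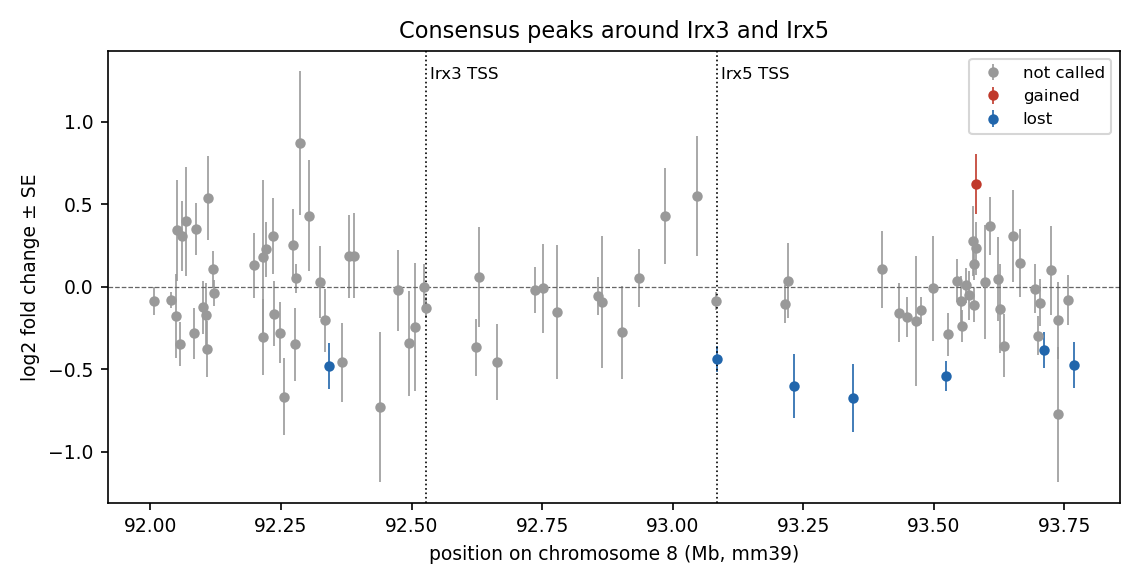
Log2 fold change of the 92 consensus peaks between 92 and 94 Mb of chromosome 8 (mm39) by position, with bars of 1 standard error implied by the deposited F and dotted lines at the start sites of Irx3 and Irx5. The 7 lost peaks are blue, among them those inside Fto, at the Irx5 promoter and downstream of Irx5, the 1 gained peak is red, and the grey peaks did not pass the edgeR FDR.

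Klf4, a zinc finger transcription factor gene, had 13 annotated peaks, all intergenic, the nearest of them -91151 bp from its start site. Of these, 2 were gained and 2 were lost in the authors' deposited table. The gained peaks (chromosome 4, 55730409 to 55730566 and 55838545 to 55838795) had log2 folds of 0.59 (SE 0.177) and 0.78 (SE 0.258) in the authors' deposited table. The lost ones (55802194 to 55802577 and 55894142 to 55894868) had log2 folds of -0.86 (SE 0.259) and -0.36 (SE 0.112) in the authors' deposited table. With the trend of fold with signal subtracted, 1 gained peak (0.78 before, 0.70 after, adjusted p 0.0914) and 1 lost peak (-0.36 before, -0.32 after, adjusted p 0.0726) no longer passed at the same standard errors. With an assumed coefficient of variation of 0.1 none of the 4 passed (adjusted p 0.314 to 0.618). Within 50 kb of the Klf4 start site, 0 of 11 consensus peaks passed the edgeR FDR, and 0 had an unadjusted p under 0.05. Ctsk, the gene of the Cre driver and of the bone matrix protease cathepsin K, gained accessibility at 2 of 3 annotated peaks. Only the knockout libraries carried the Cre. An effect of the Cre and one of the Plagl1 deletion can therefore not be told apart, at Ctsk or at any other peak, list or class. The Ctsk peak over the start site, reaching into intron 1 of 7 (chromosome 3, 95405963 to 95407420), had a log2 fold of 0.35 (SE 0.0763, FDR 0.000778) in the authors' deposited table, and the peak 12680 bp downstream had 0.32 (SE 0.104, FDR 0.0440). Of the 24 consensus peaks within 50 kb of the Klf4, Irx5 and Ctsk start sites, a set bounded without regard to p but chosen after the data were seen, 3 passed with adjustment over all peaks and 4 with adjustment over these 24 alone. With an assumed coefficient of variation of 0.1 the Irx5 promoter had an adjusted p of 0.371 and the Ctsk start site peak one of 0.549.

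The third comparison asked which groups of genes lay near changed peaks, using 23 gene lists fixed before the data were examined. Genes of the leukocyte and macrophage list and of the osteoclast list gained accessibility more often than other genes, and genes of the extracellular matrix and WNT pathway lists lost it more often. Of the 16 leukocyte and macrophage genes with an annotated peak, 12 (75%) had a gained peak, against 24.4% of other genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p 0.00138 over 46 tests), and 1 had a lost peak. Spi1, the gene of the myeloid transcription factor PU.1, had a gained promoter peak (chromosome 2, 90912285 to 90912658) with a log2 fold of 0.61 (SE 0.132, FDR 0.000708) in the authors' deposited table. The complement gene C1qb had a gained promoter peak (chromosome 4, 136613223 to 136613997) of 0.55 (SE 0.111, FDR 0.000276), and the signalling adaptor gene Tyrobp a gained intergenic peak of 0.46 (SE 0.0998, FDR 0.000850), in the authors' deposited table. Of the 14 osteoclast genes, 9 had a gained peak (64.3% against 24.4% of other genes, Fisher's exact test, adjusted p 0.0280) and 1 had a lost peak. Examples from the authors' deposited table are Clcn7, a lysosomal chloride transporter gene, with 0.68 (SE 0.122) in intron 1 of 24, and Src, a tyrosine kinase gene, with 0.54 (SE 0.0913) in intron 1 of 14. The osteoclast list shares 1 gene, Csf1r, with the leukocyte list, and Ctsk, the gene of the Cre driver, is among its 9 gained genes.

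**Figure D3:**
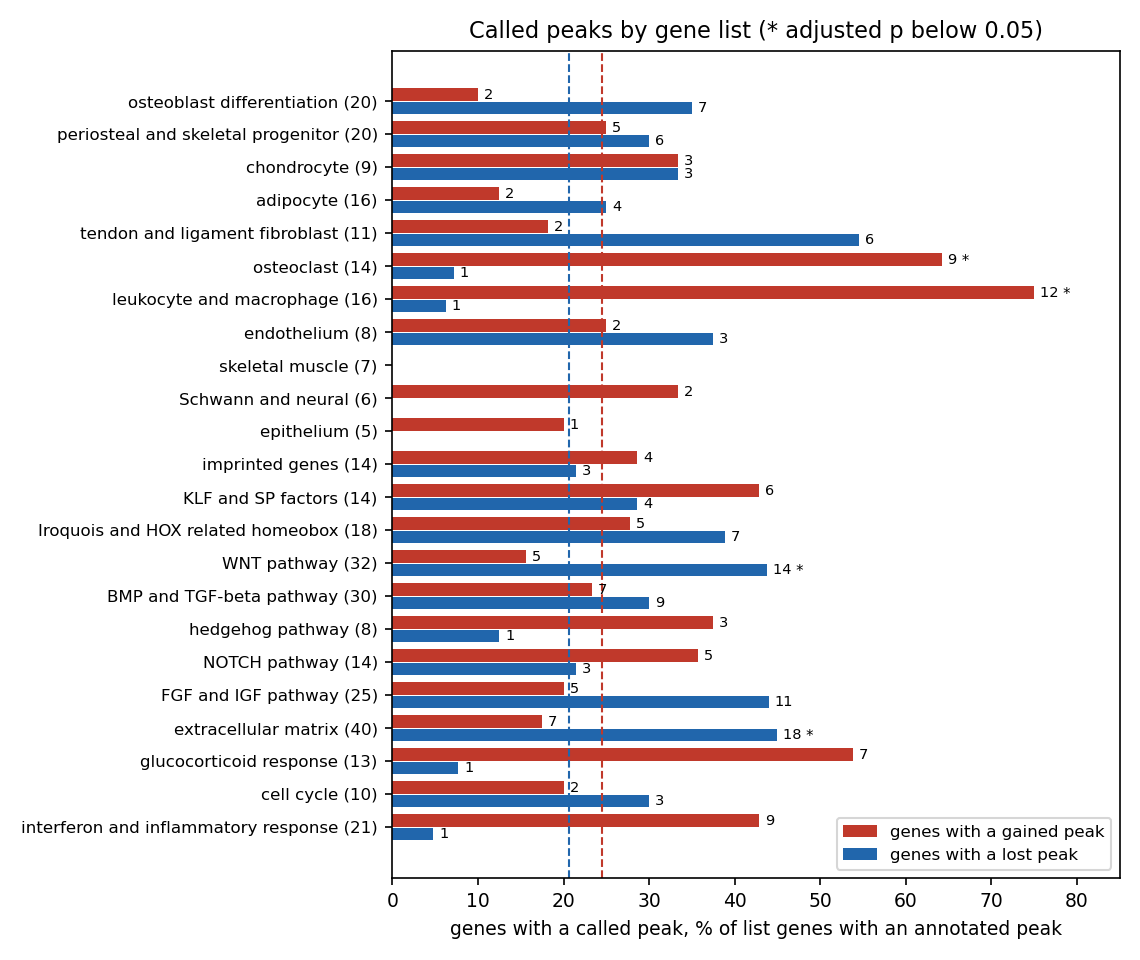
Share of each list's genes with a gained (red) or lost (blue) peak, as a percentage of its genes with an annotated peak, whose number stands in brackets. Bar labels are gene counts, dashed lines are the shares among other genes, and the 4 starred bars are the leukocyte and macrophage (12), osteoclast (9), WNT pathway (14) and extracellular matrix (18) lists.

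Of the 40 extracellular matrix genes with an annotated peak, 18 had a lost peak (45% against 20.5% of other genes, Fisher's exact test, adjusted p 0.0123) and 7 had a gained peak, 1 of them among the 18. Mmp2, a gelatinase gene, had a lost intergenic peak (chromosome 8, 93523958 to 93524580) with a log2 fold of -0.54 (SE 0.0911) in the authors' deposited table. Adamts1, a matrix protease gene, had -0.30 (SE 0.0639) in intron 1 of 8, while Col15a1, a collagen gene, gained 0.65 (SE 0.141) in intron 14 of 39, in the authors' deposited table. In the WNT pathway list 14 of 32 genes had a lost peak (43.75% against 20.5% of other genes, Fisher's exact test, adjusted p 0.0369) and 5 a gained peak, 3 of them with both. Tcf7l1, a transcription factor of the pathway, had a lost peak in exon 1 of 13 with -0.33 (SE 0.0659) in the authors' deposited table. The gained WNT examples were Sost, an inhibitor, and Axin2, a negative feedback gene, whose peak 91517 bp from its start site lies on a ribosomal RNA repeat and had a log2 fold of 0.30 (SE 0.0382) in the authors' deposited table. A nearer Axin2 peak, -2586 bp from the start site (chromosome 11, 108808322 to 108808856), went the other way, with a log2 fold of -0.54 (SE 0.158, FDR 0.02003) in the authors' deposited table. In the same comparison the leukocyte and macrophage markers had 19 gained peaks and 1 lost peak.

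The other 42 list tests did not pass. In the osteoblast differentiation list, 2 of 20 genes had a gained and 7 a lost peak (Fisher's exact test, adjusted p 0.632 and 0.612), and the examples were Phex at -0.71 (SE 0.165), Mef2c at -0.54 (SE 0.129) and Tnc at -0.43 (SE 0.104) in the authors' deposited table. In the periosteal and skeletal progenitor list the counts were 5 gained and 6 lost of 20 genes, with the promoter of the mesenchymal transcription factor gene Twist1 at -0.30 (SE 0.0674) in the authors' deposited table. Gained and lost gene counts were 3 and 3 of 9 for chondrocyte, 2 and 4 of 16 for adipocyte, 2 and 6 of 11 for tendon and ligament, and 2 and 3 of 8 for endothelium. They were 0 and 0 of 7 for skeletal muscle, 2 and 0 of 6 for Schwann and neural, and 1 and 0 of 5 for epithelium. Among regulators they were 4 and 3 of 14 imprinted genes, 6 and 4 of 14 KLF and SP factors, and 5 and 7 of 18 Iroquois and HOX related genes. Among other signalling lists they were 7 and 9 of 30 for BMP and TGF-beta, 3 and 1 of 8 for hedgehog, 5 and 3 of 14 for NOTCH, and 5 and 11 of 25 for FGF and IGF. For glucocorticoid response they were 7 and 1 of 13, for cell cycle 2 and 3 of 10, and for interferon and inflammatory response 9 and 1 of 21. Examples in the authors' deposited table are a gained peak near Dusp1, a glucocorticoid-induced phosphatase gene, at 0.48 (SE 0.0791), a gained promoter peak of the cytokine gene Tnf at 0.68 (SE 0.144), and Igf1, a growth factor gene, at 0.78 (SE 0.144) at a peak -104571 bp from its start site.

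As a description, the median over genes of the mean log2 fold of annotated peaks was -0.26 for the extracellular matrix list, at percentile 0.10 of 10000 random lists matched on peaks per gene, and -0.33 for the adipocyte list, at percentile 0.25. It was 0.43 for the leukocyte list (percentile 97.0), 0.43 for the osteoclast list (95.8) and -0.13 for the WNT list (3.15). The BMP and TGF-beta list (-0.23, percentile 0.87) and the epithelium list (-0.41, percentile 2.23) lay lower than the WNT list, though their list tests did not pass. No list test passed when an absolute log2 fold of at least 1 or an assumed coefficient of variation of 0.1 was required, and the WNT loss had an adjusted p of 0.745 with peaks within 50 kb of a start site. Only 1 list test, the leukocyte and macrophage gain, passed with promoter peaks alone. Some tests passed only in other settings. The FGF and IGF loss passed within 50 kb (odds ratio 4.25, adjusted p 0.0238) and with the trend subtracted (4.04, adjusted p 0.0163). The glucocorticoid response gain passed with the trend subtracted (5.38, adjusted p 0.0245). The interferon and inflammatory list passed when its 14 gained peaks and 1 lost peak were compared with other called peaks (odds ratio 10.5, Fisher's exact test, adjusted p 0.0199 over 23 tests). These 14 gained peaks came from 9 genes, and peaks of 1 gene are not independent. Counted by gene, the gain of this list did not pass (9 of 21 genes, Fisher's exact test, adjusted p 0.382).

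The fourth comparison asked where in the genome the changed peaks lay. Among annotated peaks, promoters held a larger share of lost peaks and a smaller share of gained peaks than of peaks that did not pass. Peaks with an absolute log2 fold under 0.2, strong ones included, carry no annotation and are absent from these shares. In the strongest 10% of peaks the median standard error was 0.0660, so annotated peaks there tend to pass. Annotated peaks that did not pass are therefore poor in strong peaks, while annotated promoter peaks are strong (median log2 CPM 3.98 against 2.75 elsewhere). Odds ratios and p-values against peaks that did not pass can thus reflect the annotation rule. Of the 1989 annotated lost peaks, 399 (20.1%, exact interval 18.3 to 21.9%) lay within 1 kb of a start site, against 9.85% of the 10557 annotated peaks that did not pass (odds ratio 2.30, Fisher's exact test, adjusted p 1.31e-33). Of the 2675 annotated gained peaks, 176 (6.58%) did so (odds ratio 0.644, adjusted p 3.12e-07). Introns held 40.6% of lost peaks (odds ratio 0.808, adjusted p 4.53e-05) and intergenic regions held 36.0% (odds ratio 0.836, adjusted p 0.000845), and the other 4 class tests did not pass. CpG islands were annotated at 69 lost and 10 gained peaks. With the trend of fold with signal subtracted, the odds ratio of lost peaks was 0.976 for promoters (Fisher's exact test, adjusted p 0.935), 1.03 for introns and 1.00 for intergenic regions, and none of these 3 tests passed. At an FDR under 0.01 the lost introns no longer passed (0.847, adjusted p 0.0648). Intergenic regions then held more gained peaks than peaks that did not pass (odds ratio 1.213, adjusted p 0.00977). Peaks are not independent replicates, and the gained promoter odds ratio was 0.942 (adjusted p 0.395) with a promoter width of 3 kb and 0.179 (adjusted p 0.230) with an assumed coefficient of variation of 0.1.

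The last comparison covered the sex chromosomes and was planned to check whether the sex of the animals may differ between groups. Peaks on the X chromosome were called less often than autosomal peaks: 19 of 1693 were lost (1.12% against 2.51%, odds ratio 0.441, Fisher's exact test, adjusted p 0.000197) and 38 were gained (2.24%, odds ratio 0.704, adjusted p 0.0343). The median log2 fold was 0.00 on the X and on the autosomes. The Y chromosome held 13 peaks, of which 2 were gained and 2 were lost, all 4 beyond 80 Mb and named after their values were seen. The 3 assigned to G530011O06Rik had log2 folds of 0.63 (FDR 9.58e-06), -0.60 (FDR 1.67e-08) and -0.84 (FDR 0.0357), and the 1 assigned to Erdr1x had 0.48 (FDR 7.81e-06), in the authors' deposited table. The 4 Y peaks below 80 Mb, at Eif2s3y, Uty and Ddx3y and at 1 unannotated site, had log2 folds from -0.66 to -0.41 in the authors' deposited table, none past the edgeR FDR (smallest FDR 0.0589). All 4 lay below 0, with unadjusted edgeR p-values of 0.00371 at Eif2s3y, 0.0134 at Uty, 0.00629 at Ddx3y and 0.0887 at the other. A different mix of male and female animals between the groups can therefore not be excluded, and it could affect every comparison here. The gained X odds ratio was 0.652 (adjusted p 0.137) at an FDR under 0.01 and 2.16 (adjusted p 0.488) with an assumed coefficient of variation of 0.1. The lost X odds ratio was 0.681 (adjusted p 0.111) with the trend subtracted and 0 with that coefficient of variation.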

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

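Trend subtraction, assumed coefficients of variation, repeats left out, the stricter FDR for the direction, the turned ratio, the comparison of gained with lost peaks, the adjustment over peaks near the Klf4, Irx5 and Ctsk start sites and the rule that an odds ratio of 0 gives no direction were chosen after seeing the data, and the cause of the changes below was not tested unless stated. No paired analysis was possible because the tables give no values per library, and for the same reason leaving out replicates, other normalizations and DESeq2 were not run, nor were motifs, which need an mm39 genome. Against 4833 changed peaks, 1668 passed at an FDR under 0.01 (gained share 60.1%), 270 with an absolute log2 fold of at least 1, and 17055 at an unadjusted p under 0.05, by the construction of these thresholds. With trend subtraction the count was 4055 and the gained share 67.3% against 55.8%. With the ratio read as control over knockout the gained share would be 44.2%, by construction, and every other share would turn likewise. Centring the fold (4971), or leaving out the peaks of lowest signal (5064), kept the count within 1.5 times. Adding an assumed coefficient of variation to each standard error gave 1341 peaks at 0.05 (gained share 69.5%), 55 at 0.1 (87.3%) and 0 at 0.2, which leaves no share. The deposited standard errors fell with signal as counting noise does, but their level cannot be set against counting noise without the depth of each library. Of the 98 named peaks, 82 passed as deposited. At 0.1, 68 of these no longer passed, against 13 at an FDR under 0.01 and 4 with trend subtraction.

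The gained promoter odds ratio was 0.942 with 3 kb promoters, and the gained X odds ratio 0.652 at an FDR under 0.01, both no longer past the threshold. With trend subtraction the lost promoter odds ratio was 0.976, and those of lost introns (1.03) and lost intergenic peaks (1.00) crossed 1 too, while the lost X odds ratio was 0.681, and none of them passed. At an assumed coefficient of variation of 0.1 the odds ratio was 0.179 for gained promoters, 0 for lost promoters, 7.22 for lost introns, 2.16 for gained X peaks and 0 for lost X peaks, none past the threshold. At an FDR under 0.01 the odds ratio of gained introns was 0.982 and that of lost exons 1.11, on the other side of 1 from the main values, and neither passed in either setting. Lost introns no longer passed (0.847, adjusted p 0.0648) and gained intergenic peaks newly did (1.213, adjusted p 0.00977). Of the 46 list tests, 4 passed in the main setting, 4 within 50 kb, 6 with trend subtraction, 4 without repeats, 5 of 23 when gained were compared with lost peaks, 1 with promoter peaks alone, 0 with an absolute log2 fold of at least 1 and 0 at an assumed coefficient of variation of 0.1. In the last pair of settings the leukocyte and osteoclast gains and the matrix and WNT losses had 0 genes, so an odds ratio of 0, which gives no direction because few peaks were left. With promoter peaks alone, lists that held no gene with such a peak were not tested, so fewer than 46 tests were run. The WNT loss left within 50 kb as the FGF and IGF loss entered (4.25). The trend setting added that loss (4.04) and the glucocorticoid gain (5.38), and the comparison of gained with lost peaks added the interferon and inflammatory list (10.5). The comparison of gained with lost peaks counts peaks of 1 gene as if they were independent. The osteoclast gain (odds ratio 12.5), the matrix loss (2.11) and the WNT loss (2.95) did not pass with promoter peaks alone, nor did the WNT loss within 50 kb (1.63).

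Among gene lists, odds ratios that crossed 1 belonged to tests that passed in neither setting. Within 50 kb they were 0.412 for progenitor gained, 0.472 for chondrocyte gained, 0.661 for Schwann and neural gained, 1.10 for epithelium gained, 0.991 and 0.387 for imprinted gained and lost, 0.661 for Iroquois and HOX gained, 0.929 for NOTCH lost and 0.581 for cell cycle lost. With trend subtraction they were 0.838 for progenitor gained, 0.859 for adipocyte lost, 0.479 for endothelium gained, 0.462 for imprinted lost, 0.958 for Iroquois and HOX gained, and 2.24 and 0.668 for cell cycle gained and lost. Without repeats they were 0.904 for progenitor gained, 1.13 for BMP and TGF-beta gained and 0.686 for NOTCH lost. Epithelium gained had 9.16 with an absolute log2 fold of at least 1, and WNT gained 5.80 at a coefficient of variation of 0.1, each from 1 gene. Signal limits the calls: the median standard error of the log2 fold was 0.359 in the weakest 10% of peaks and 0.0660 in the strongest. Simulated log2 folds of 0.5 were called in 34.5% of cases when 200 peaks were changed. That share may be higher in the data, where more peaks passed and the p threshold after adjustment was less strict.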

Other observations

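The genes and lists in these paragraphs, the tests on other cell types, on the trend and of the Twist1 promoter, and the assumed coefficients of variation were chosen after the results were seen; the tests on the second myeloid list and on the peaks around the second mesenchymal genes were written down before their values were seen. Several genes had clusters of changed peaks. The authors' deposited table had 25 genes with 5 or more gained peaks, 21 of them with no lost peak. The most gained peaks lay at 4930431F10Rik (8) and Tns3 (7, with 1 lost). Genes with 6 were 1700027F09Rik, A630001O12Rik, 4930563J15Rik, Lcp2, Nrp2 and Eepd1 (with 1 lost). Examples with 5 were Lgmn, Ptafr, Rin3, Kcnk13, Cxcr4, Fos, Rbpj, Tnfaip3, Nav2, Abr, Firre and Sfi1. Lcp2 encodes an adaptor of immune receptor signalling, Lgmn a lysosomal protease and Tnfaip3 an inhibitor of NF-kappaB signalling. There were 10 genes with 4 or more lost peaks in the authors' deposited table, among them Plpp3 with 6, and Cxcl12, a stromal chemokine gene, Thbs2, Adamts9, Gpc6, Eml1 and Smad3 with 4 each, where Smad3 also had 1 gained peak.

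Repeats were unevenly spread over the called peaks. LTR elements were annotated at 8.67% of gained and 3.37% of lost peaks (odds ratio 2.72, Fisher's exact test, two-sided, p 4.85e-14, unadjusted). Annotated LTR peaks were weaker than those outside repeats (median log2 CPM 2.36 against 2.93), and this test was not repeated with the trend of fold with signal subtracted. LINE (117 gained, 39 lost) and SINE elements (95 gained, 41 lost) leaned the same way, while DNA repeats were even (22 gained, 22 lost). Satellite and ribosomal RNA repeats were annotated at 14 gained and 0 lost peaks and at 5 of the 20 annotated peaks with the smallest p, such as a peak assigned to Lrrc4c on chromosome 2 (98492586 to 98493208), with a log2 fold of 0.71 and an FDR of 9.43e-46 in the authors' deposited table. Reads of such repeats map to many places, and no explanation was tested.

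The first pattern weighed was gained peaks at leukocyte genes: in a second myeloid list of 65 genes, none of them in the fixed lists, 46 of 49 called peaks were gained (93.9%, exact interval 83.1 to 98.7%, against 57.0% of other called annotated peaks, Fisher's exact test p 1.41e-08), and 123 of its 135 annotated peaks (91.1%) had a fold above 0 against 56.4% of others, in line with more myeloid cells in the knockout cultures as a hypothesis if positive folds mean higher in the knockout, and with fewer if the ratio is turned. The 135 annotated peaks of the second myeloid list belong to 54 genes, and its interval and p treat peaks of 1 gene as independent. No test with 1 peak per gene was run for that list. Against the trend with signal, 18 of 19 gained leukocyte peaks (94.7%) passed after its subtraction. The median log2 fold was 0.48 before and 0.49 after, although 0 of the 19 passed at an assumed coefficient of variation of 0.1. Gained peaks at C1qb (15.1 CPM), Spi1 (10.9) and Tyrobp (18.8), rose 1.46-, 1.53- and 1.37-fold in the authors' deposited table, and the labels name no sort that would remove such cells. A lower stromal share that raises every other cell type alike cannot be told apart from a rise of myeloid cells. Endothelium, muscle, Schwann and epithelium peaks together were gained in 50% of 10 called peaks (exact interval 18.7 to 81.3%), against 95% of the leukocyte list (Fisher's exact test p 0.00884). All 5 losses were endothelial (2 gained, 5 lost), 3 of them at the single gene Erg, while Schwann (2 gained, 0 lost) and epithelium (1 gained, 0 lost) went the leukocyte way and muscle had 0 called peaks. Peaks of 1 gene are not independent, and with 1 peak per gene the counts were 4 gained and 2 lost against 12 and 1 (Fisher's exact test p 0.222). Lymphocyte (4 gained, 2 lost) and erythroid and megakaryocyte peaks (3 gained, 1 lost) were too few as well. A change within myeloid or osteoclast lineage cells, in which Ctsk-iCre may also act, and a difference between the few cultures stay open and were not tested.

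The second pattern was lost peaks at Irx5: if all stromal elements had fallen alike, peaks within 10 kb of the start sites of second mesenchymal genes would have fallen by about as much as Irx5, and their median log2 fold was -0.084 (SE 0.0364, 79 peaks of 26 genes, with 2 gained and 4 lost), above the upper 95% limit of the Irx5 promoter (-0.29). Only 17.7% of these peaks lay below that limit. By the prediction written before, these values argue against a fall of all peaks around these genes as large as that of the Irx5 promoter. The test set 1 called Irx5 peak against all peaks of the other genes. By a more similar measure, over the 3 consensus peaks within 50 kb of its start site, Irx5 had a median log2 fold of -0.0875. The test therefore cannot decide whether the Irx5 locus fell more than these genes did. These values also do not cover stroma-specific peaks alone, because many peaks around these genes may be open in other cells too. The promoter of Twist1, a stromal gene picked after its value was seen, had -0.30 (SE 0.0674) in the authors' deposited table, and differed from Irx5 by 0.14 (SE 0.103). The promoters of Cxcl12 (-0.20, SE 0.0606) and Fbn2 (-0.43, SE 0.121), also picked afterwards, lay on either side of Twist1. A fall of stroma-specific elements and a loss specific to Irx5 cannot be told apart for this promoter. Among called peaks of the second mesenchymal list, which shares 6 genes with the fixed lists, 12 were gained and 19 lost (38.7% gained, Fisher's exact test p 0.0441, unadjusted). A direct effect of PLAGL1 or KLF4 on Irx5 stays open and was not tested, as no motif or binding data were used here.

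The third pattern was that weaker peaks were gained and stronger peaks lost. Peaks with a deposited p of at least 0.05 showed it too: their median log2 fold was 0.08 in the weakest 10% and -0.04 in the strongest 10%, a difference of 0.12. This is consistent with a library-wide difference in signal to background between the genotypes, such as the share of reads in peaks, as a candidate explanation. A change of the same form across the genome in the knockout cells would look alike, and values per library were not used here to separate them. Annotated promoter peaks were stronger than other annotated peaks (median log2 CPM 3.98 against 2.75). The loss at promoters (odds ratio 2.30) ended with the trend subtracted (0.976), so that loss may be this trend, and the annotation rule may add to it. The lower share of promoters among gained peaks then had an odds ratio of 0.637, over the 2554 gained peaks with an annotation. Annotation required a deposited absolute log2 fold of at least 0.2, which leaves out strong peaks with small folds. Whether that lower share outlasts the trend over all peaks cannot be told from annotated peaks.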
